A study of Fagopyrum tataricum with 9 samples.

How the data were processed

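Seeds of the Tartary buckwheat variety MIQIAO 1 were sampled at 13, 19 and 25 days post anthesis (dpa), per the labels' protocols, and RNA was sequenced in 3 libraries for each of 3 stages called green fruit, discoloration and initial maturity. The labels do not tie each day to a stage name; the days were matched to the stages in developmental order. Seeds of the 3 stages came from the same individual and 3 plants made up the 3 replicates, per the labels, but no label says that a replicate number marks a plant. Libraries were made with the Illumina TruSeq RNA kit, which does not mark the strand, so reads of a gene and of a gene on the opposite strand at the same place could not be told apart.

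The authors deposited read counts per gene, per the file headers, for 31839 gene models and 2092 genes of their own outside the reference annotation, 33931 in all; 3822 of these had no count in any library. Bowtie2 2.0.6 and TopHat2 2.0.12 are named by the submitters' processing notes. The program that counted reads, the genome build and the annotation release are not given in the sources used here, so positions are those of the deposited gene descriptions. Whether reads matching several genes were counted is likewise not given, so values of near-identical gene copies, among them the 13S globulin genes and the antimicrobial peptide genes on chromosome 6, are uncertain. The authors also deposited FPKM values (fragments scaled to gene length and library size), per the file headers. Of 239659 FPKM values above 0, 87.29% equalled the count scaled to gene length and to the total of the library's counts within a relative tolerance of 0.001, so these values carry no correction for a change in composition.

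The authors' deposited gene table further holds log2 ratios and p-values, with their adjusted p-values, for the 3 pairs of stages; the test behind the p-values is not given in the sources used here. The log2 ratios are of the earlier over the later stage, as their correlation with the same ratios of the deposited counts shows (r of at least 0.999), and were turned around for comparison. The same table pairs gene IDs with Swiss-Prot matches. A match was present for 23452 gene models, and gene names given here are the names of those best matches, not names of characterised buckwheat genes. The deposited variant tables give genotype calls at 83860 SNP and 23098 InDel sites, with a number from 2 to 99 after each call whose meaning the file headers do not state. Each of these 2 tables also has 9 columns that match no sample here, which were not used. The deposited annotation of the authors' own genes gave only positions.

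Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3 (glmQLFit and glmQLFTest on TMM-scaled counts, filterByExpr with its minimum count of 10). All 9 libraries entered 1 fit, without a replicate term, and contrasts gave the 3 comparisons of stages, the difference between the 2 intervals and an F test over the 3 stages. The filter left 23631 genes and removed 10300. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05. The common biological coefficient of variation was 0.289 and the median prior degrees of freedom were 3.36. Each SE given is the absolute log2 fold change divided by the square root of the F statistic of its test. It restates that test and is not a separate estimate of the error of the fold. Levels are TMM-scaled CPM (counts scaled to library size), as mean ± SD of n = 3 libraries. The depth was 21585045 to 26777643 counts per library.

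Before the data were examined, 32 gene lists were fixed as text patterns, matched to the Swiss-Prot names: phenylpropanoid entry, monolignol synthesis, laccase, class III peroxidase, secondary wall cellulose and xylan, secondary wall regulators, primary wall growth, pectin modification, flavonol synthesis, anthocyanin and proanthocyanidin synthesis, starch synthesis, starch degradation, sucrose transport and cleavage, storage proteins, LEA and dehydrin proteins, oil bodies and triacylglycerol, small heat shock proteins, seed maturation regulators, abscisic acid, gibberellin, ethylene, photosynthesis, chlorophyll breakdown, cell division, cytosolic ribosome, programmed death and senescence, fruit dehiscence and identity, protease inhibitors, antioxidant enzymes, and markers of pollen and flower, endosperm and embryo, and vascular tissue. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over 96 tests (32 lists, 3 comparisons). The same test was repeated with the correlation estimated for each list. List medians are given as the log2 median of the members minus the median of all genes tested. The interval difference of lists was adjusted over the 32 lists.

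Single genes were named by a rule fixed before the data were examined. For each adjacent comparison it took the 5 highest and 5 lowest log2 fold changes among annotated genes with adjusted p under 0.05, a mean CPM of at least 10 and no overlap between the libraries of the 2 stages. It also took, from the 10 lists with the most members past the threshold (at least 3), the member past it with the highest mean CPM and that with the largest absolute change among members with a mean CPM of at least 10. For initial maturity against green fruit only the first part applied. Genes named outside this rule are said to be so.

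Where all 3 libraries of a stage had 0 counts, the fold is a bound against a floor of 3 counts over the group. Where a stage had 1 to 3 counts, the ratio is given with an exact 95% interval. Both cover counting error only, since PCR copies are not independent molecules. Genotype calls were compared as the share of sites with equal calls, with an exact permutation test over the 36 ways to match replicate numbers across the 3 stages (one-sided).

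The fit was tested on simulated counts drawn from the means and library sizes of the real genes, with 200 genes changed (50 per fold). For discoloration against green fruit, over 22913 genes, 4% of the 2-fold, 80% of the 4-fold, 86% of the 8-fold and 84% of the 16-fold changes were recovered, with 5 false calls among 132. For initial maturity against discoloration, over 22983 genes, the shares were 16%, 64%, 94% and 90%, with 8 false calls among 140. For initial maturity against green fruit, over 22887 genes, they were 16%, 56%, 86% and 98%, with 11 false calls among 139. With only 200 genes changed the threshold on p is stricter than in the real comparisons, so these shares do not carry over to them. Counts drawn from means and library sizes also lack the closely similar pair of libraries that each real stage holds, described below. The false calls therefore cannot show how often the fit errs on the real libraries.

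Alternatives were DESeq2 1.42.0 and its size factors, upper-quartile factors, library totals without further scaling, 2 other count filters, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other thresholds, the 50 most-counted genes or the genes outside the reference annotation left out, a replicate block, and each library left out in turn. For lists, limma's fry was also run, which tests the members against no change rather than against other genes. The list patterns were also matched to another description field, the deposited KEGG text, which was present for 11947 gene models. It gave other, mostly smaller sets of genes, such as 8 ribosome genes against 319 by Swiss-Prot names. A call lost or gained there may reflect the different set of genes. The closing section gives their effect. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, which also read the tables with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.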

Results

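Gene expression was measured by RNA sequencing in developing seeds of MIQIAO 1, a Tartary buckwheat (Fagopyrum tataricum) grown for grain whose hull comes off easily. The 9 libraries fell into 3 stages of 3 libraries each: green fruit (13 dpa), discoloration (19 dpa) and initial maturity (25 dpa). Green fruit libraries held 24273191, 26777643 and 21585045 counts, discoloration libraries 23755258, 25453985 and 24292418, and initial maturity libraries 22153606, 24945512 and 22488709. A few genes took a growing part of these counts. The 20 most-counted genes of a library held 11.5 ± 4.36% of its counts in green fruit, 40.8 ± 1.85% at discoloration and 45.1 ± 2.90% at initial maturity (mean ± SD, n = 3). Genes of seed storage proteins alone (15 genes, those left out whose names show another function) held 5.26 ± 3.57%, 25.5 ± 0.783% and 23.0 ± 6.41%.

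Libraries of different stages lay apart on the first principal component, which held 71.4% of the variance. Within each stage, however, 1 library stood apart from a pair of closely similar ones. Green fruit libraries 2 and 3, discoloration libraries 2 and 3 and initial maturity libraries 1 and 3 differed from each other with a chi-square per degree of freedom of 2.63, 2.02 and 3.7 over genes. The remaining library of the stage differed from these with values of 271 and 246, 45.5 and 45.2, and 115 and 120. The close pairs thus differed by more than sampling noise and were kept as separate libraries, but the p-values below measure the spread between these libraries, which may be partly technical. Storage protein genes moved with the libraries that stood apart in 2 of the stages: their share was 9.38% in green fruit library 1 against 3.15% and 3.26% in libraries 2 and 3, and 15.56% in initial maturity library 2 against 26.44% and 26.86% in libraries 1 and 3. At discoloration it was 26.43% in library 1 against 25.15% and 25.01%. Other lists also varied widely among green fruit libraries, with shares of 0.0426% to 0.28% for secondary wall cellulose and xylan genes, 0.0344% to 0.132% for laccase genes and 0.483% to 1.48% for photosynthesis genes.

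**Figure D1:**
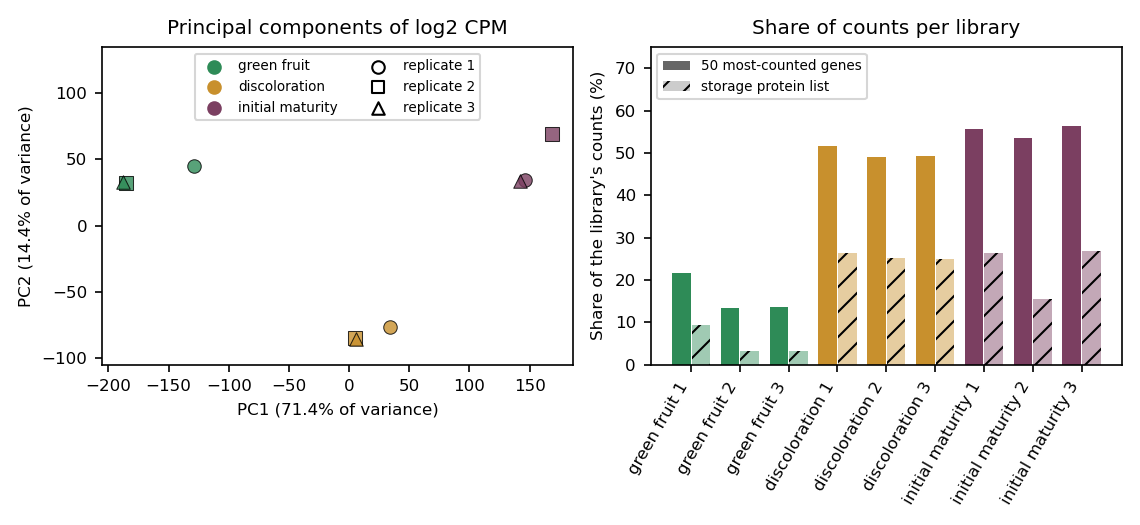
The left panel plots the 9 libraries on the first 2 principal components of log2 CPM (colour for stage, symbol for replicate number), and the right panel gives as bars the share of each library's counts, in percent, in its 50 most-counted genes and in these 15 storage protein genes. The 50 most-counted genes held 13.28% to 21.57% of the counts in green fruit libraries and 48.99% to 56.27% in the later ones.

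Between green fruit and discoloration, most genes of small heat shock proteins, storage proteins and oil bodies rose. Most genes of photosynthesis, cell division and primary wall growth fell. Small heat shock protein genes, chaperones that accumulate in maturing seeds, rose: 25 of 30 members tested were higher at discoloration and 1 was lower, with 28 past the threshold adjusted over the list alone and a median log2 change 5.23 above that of all genes (camera, adjusted p = 3.5e-37). This list's call was lost when the correlation was estimated (adjusted p = 0.118 with an estimated correlation). The 18.1 kDa class I heat shock protein gene (FtPinG0008433900.01, chromosome 1, 33609905 to 33610476) rose from 299 ± 172 to 8953 ± 294 CPM, a log2 fold change of 4.90 (SE 0.59, adjusted p = 3.5e-04). A chloroplastic small heat shock protein gene (FtPinG0007566000.01, chromosome 2, 33754684 to 33755905) rose from 0.775 ± 0.453 to 729 ± 118 CPM (log2 fold change 9.88, SE 0.56, adjusted p = 1.0e-05).

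Genes of oil bodies and storage proteins rose in the same step. Of 26 oil body and triacylglycerol genes 18 rose and 3 fell, with 22 past the threshold adjusted over the list alone (median 2.33 above all genes, adjusted p = 3.5e-06, and adjusted p = 0.364 with an estimated correlation). Of 23 genes in the storage protein list 12 rose and 4 fell, with 19 adjusted over the list alone (median 1.88, adjusted p = 0.00551, and adjusted p = 0.627 with an estimated correlation). The list holds genes named for protease-like proteins. Of the 14 tested genes without these 10 rose, 12 adjusted over the list alone (median 2.93, adjusted p = 3.4e-05, and adjusted p = 0.565 with an estimated correlation). LEA and dehydrin genes, whose proteins protect drying cells, had 15 of 30 members higher and 3 lower, 21 adjusted over the list alone (median 0.87, adjusted p = 0.00714, and adjusted p = 0.611 with an estimated correlation). Without members matched only inside a longer word 12 of 20 were higher and 3 lower, 17 adjusted over the list alone (median 2.10, adjusted p = 0.00823, and adjusted p = 0.565 with an estimated correlation). Protease inhibitor genes had 11 of 25 higher and 6 lower, 21 adjusted over the list alone (median 1.21, adjusted p = 0.0133, and adjusted p = 0.627 with an estimated correlation). A pair of genes matching antimicrobial peptide 1 on chromosome 6 were among the 5 largest rises. FtPinG0004979700.01 (45236072 to 45236497) went from 7.29 ± 6.17 to 4765 ± 2050 CPM (log2 fold change 9.35, SE 1.57, adjusted p = 0.00186), and FtPinG0004980500.01 (45253326 to 45253743) from 0.801 ± 0.656 to 1095 ± 368 CPM (10.41, SE 1.03, adjusted p = 1.4e-04). Reads may be shared between such neighbouring copies.

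Flavonoid and ethylene lists passed the list test upward. Of 47 genes in the anthocyanin and proanthocyanidin list 20 rose and 5 fell, with 28 adjusted over the list alone (median 0.92, adjusted p = 0.00221, and adjusted p = 0.238 with an estimated correlation). Most of its matches are named for a transporter of a large family. Of the 18 tested genes without these 10 rose and 1 fell, 12 adjusted over the list alone (median 1.18, adjusted p = 4.6e-04, and adjusted p = 0.389 with an estimated correlation). Of 18 flavonol genes 6 rose and 0 fell, with 6 adjusted over the list alone (median 0.81, adjusted p = 0.0351, and adjusted p = 0.627 with an estimated correlation). Both list calls were lost without green fruit library 1 (adjusted p = 0.071 and 0.122), and that of flavonol genes also without discoloration library 1 (adjusted p = 0.0507). Of 130 ethylene synthesis and response genes 45 rose and 24 fell, with 71 adjusted over the list alone (median 0.28, adjusted p = 0.0147, and adjusted p = 0.611 with an estimated correlation), and the adjusted p was 0.0688 with members left out whose names show another function. With list members taken from another description field none of these lists passed (adjusted p = 0.222 for anthocyanin, 0.21 for flavonol and 0.764 for ethylene genes, the last with a median of -0.34). That field matched 6, 18 and 16 genes for these lists, against 88, 29 and 183 by Swiss-Prot names. The beta-fructofuranosidase gene FtPinG0003938000.01, a sucrose-cleaving cell wall enzyme, rose from 0.321 ± 0.128 to 20.9 ± 1.87 CPM (log2 fold change 6.02, SE 0.26, adjusted p = 5.1e-06). A sucrose synthase gene, FtPinG0005125200.01, fell from 2096 ± 1830 to 127 ± 23.7 CPM (log2 fold change -4.04, SE 0.59, adjusted p = 9.4e-04), while sucrose synthase 2, FtPinG0008844900.01, rose from 25.2 ± 9.81 to 307 ± 65.1 CPM (3.61, SE 0.34, adjusted p = 1.2e-04). Some genes had 0 counts in all green fruit libraries. Beta-glucosidase 17 (FtPinG0003438100.01) was at least 582-fold higher at discoloration, (R,S)-reticuline 7-O-methyltransferase (FtPinG0006556600.01) at least 226-fold and ethylene-responsive factor ERF098 (FtPinG0009155900.01) at least 86.3-fold.

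Most genes of the photosynthesis, cell division and primary wall growth lists fell. None of 55 photosynthesis genes rose and 43 fell, with 47 adjusted over the list alone (median -1.81, adjusted p = 4.4e-13, and adjusted p = 0.611 with an estimated correlation). The Rubisco small chain gene FtPinG0008981900.01 fell from 983 ± 476 to 172 ± 19.8 CPM (log2 fold change -2.51, SE 0.47, adjusted p = 0.00304). Of 95 cell division genes 4 rose and 69 fell, with 76 adjusted over the list alone (median log2 change -2.04 as fitted, adjusted p = 5.7e-11, and adjusted p = 0.627 with an estimated correlation). Histone H3.3 (FtPinG0005843900.01) was among those that rose, from 149 ± 3.23 to 225 ± 19.8 CPM (0.60, SE 0.17, adjusted p = 0.0213), but its log2 fold change was -0.39 with library totals only, and the call was lost without green fruit library 2 or 3 or any 1 discoloration library (adjusted p = 0.0562 to 0.0718). Primary wall growth genes had 7 of 57 higher and 32 lower, 43 adjusted over the list alone (median -1.26, adjusted p = 6.7e-04, and adjusted p = 0.611 with an estimated correlation). Expansin-A15, FtPinG0004679600.01, a wall-loosening protein, fell from 158 ± 96.5 to 1.88 ± 1.28 CPM (-6.38, SE 0.86, adjusted p = 6.2e-04). The called member with the highest mean CPM, xyloglucan endotransglucosylase 23 (FtPinG0003957900.01), rose instead, from 10.7 ± 11.6 to 561 ± 53.7 CPM (5.72, SE 0.76, edgeR adjusted p = 5.7e-04). Secondary wall cellulose and xylan genes had 1 of 30 higher and 17 lower, 19 adjusted over the list alone (median -1.46, adjusted p = 0.00222, and adjusted p = 0.663 with an estimated correlation). Laccase-17 (FtPinG0008390000.01), of a family that polymerises lignin, fell from 87.3 ± 59.6 to 0.450 ± 0.248 CPM (-7.57, SE 1.02, adjusted p = 6.1e-04). The laccase list had 2 of 19 higher and 11 lower, 14 adjusted over the list alone, and did not pass (median -2.59, adjusted p = 0.0671, and adjusted p = 0.663 with an estimated correlation). It passed with the replicate number as a block (adjusted p = 0.00305), with close pairs added together (0.0427), and without green fruit library 1 (1.5e-04) or initial maturity library 1 or 3 (0.0283 and 0.0371). Another test, fry, sets the members against no change rather than against other genes; there the adjusted p was 0.0493 for laccase, 0.0545 for secondary wall and 0.52 for ribosome genes. Pectin modification genes had 13 of 88 higher and 33 lower, 51 adjusted over the list alone (median -0.51, adjusted p = 0.0109, and adjusted p = 0.627 with an estimated correlation). Both members named by the rule rose. Pectinesterase 2 (FtPinG0000270200.01) went from 15.3 ± 7.13 to 202 ± 112 CPM (3.72, SE 0.51). Pectinesterase/inhibitor 36 (FtPinG0005031600.01) went from 2.19 ± 2.60 to 79.7 ± 2.43 CPM (5.20, SE 0.74). Cytosolic ribosome genes had 4 of 286 higher and 28 lower, 8 adjusted over the list alone (median -0.31, adjusted p = 0.0465, and adjusted p = 0.921 with an estimated correlation). The ribosome call was lost without discoloration library 1 or any 1 initial maturity library (adjusted p = 0.0664 to 0.206), and without green fruit library 1 the median was 0.18 (adjusted p = 0.486). It was also lost with the replicate number as a block. Summed CPM fell over the 3 stages for photosynthesis (6381, 1683 and 243) and secondary wall cellulose and xylan genes (1106, 258 and 155). It moved less for cell division (2520, 2103 and 2253), primary wall growth (2374, 2083 and 2114) and pectin genes (1283, 1171 and 1128). For laccase genes the summed CPM was 551.7, 403.7 and 449.6.

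In all, 9326 of 23631 genes differed between discoloration and green fruit, 4615 higher and 4711 lower. The count was 2877 with the closely similar pair of each stage added together as 1 library, and 17730 with the libraries standing apart left out, both chosen after seeing the data. With library totals only, 17967 genes differed and 10.2% of them were higher, against 49.5% here, as the median log2 change of all genes moved from -0.041 to -1.027, and the secondary wall, primary wall and pectin lists no longer passed (adjusted p = 0.181, 0.293 and 0.459). Their medians against all genes were then -1.52, -1.21 and -0.51. With list members taken from another description field the storage protein test pointed down (adjusted p = 0.547), and the pectin and ribosome lists no longer passed (adjusted p = 0.0754 and 0.471). That field matched only 44 pectin and 8 ribosome genes, against 165 and 319 by Swiss-Prot names, so these are tests of much smaller lists.

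From discoloration to initial maturity photosynthesis genes fell further and the flavonol list fell too. Of 55 photosynthesis genes 1 rose and 47 fell, with 51 adjusted over the list alone (median -3.18, adjusted p = 2.7e-30, and adjusted p = 0.364 with an estimated correlation), and Rubisco small chain FtPinG0008981900.01 went from 172 ± 19.8 to 18.1 ± 7.61 CPM (log2 fold change -3.25, SE 0.49, adjusted p = 0.0014). Of 18 flavonol genes 1 rose and 15 fell, with 16 adjusted over the list alone (median -2.04, adjusted p = 9.6e-07, and adjusted p = 0.364 with an estimated correlation). The anthocyanin and proanthocyanidin list had 7 of 47 higher and 20 lower, 27 adjusted over the list alone (median -1.11, adjusted p = 0.0447, and adjusted p = 0.364 with an estimated correlation), a call lost without green fruit library 2, discoloration library 1 or 3 or any 1 initial maturity library (adjusted p = 0.0514 to 0.169). It was also lost with the 61 of 88 matched genes left out that are named for the transporter (3 of 18 higher and 6 lower, 9 adjusted over the list alone, median -0.23, adjusted p = 0.396), with another description field (adjusted p = 0.0544), and with the replicate number as a block. The other description field matched only 6 genes for this list. Leucoanthocyanidin dioxygenase, FtPinG0006306200.01, which makes anthocyanidins, fell from 377 ± 51.6 to 44.4 ± 16.5 CPM (-3.09, SE 0.47, adjusted p = 0.00144). Chlorophyll breakdown genes had 1 of 15 higher and 8 lower, 9 adjusted over the list alone (median -0.51, adjusted p = 0.0191, and adjusted p = 0.627 with an estimated correlation), a call lost without discoloration library 1 (adjusted p = 0.058).

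The class III peroxidase, monolignol and pectin lists also passed the list test downward in this step, but only at the preset correlation. In each of these lists most members did not pass on their own with adjustment over all genes. Those that passed were mostly lower at initial maturity. Laccase, primary wall growth, secondary wall cellulose and xylan, and secondary wall regulator genes did not pass the list test (adjusted p = 0.171, 0.0638, 0.384 and 0.299). Primary wall growth genes passed downward with the replicate number as a block (adjusted p = 0.0295), with close pairs added together (0.0337), with another description field (0.0429) and without green fruit library 3 (0.0492), discoloration library 1 (0.00564) or initial maturity library 3 (0.0342). Against no change rather than other genes (fry) the adjusted p was 0.0353 for primary wall, 0.0291 for laccase and 0.0136 for secondary wall regulator genes. Class III peroxidase genes had 0 of 36 higher and 17 lower, 19 adjusted over the list alone (median -1.70, adjusted p = 1.1e-04, and adjusted p = 0.547 with an estimated correlation). Peroxidase 55 (FtPinG0004712400.01) fell from 123 ± 8.55 to 4.02 ± 1.40 CPM (log2 fold change -4.93, SE 0.38, adjusted p = 1.3e-04). Monolignol synthesis genes had 7 of 60 higher and 22 lower, 32 adjusted over the list alone (median -0.79, adjusted p = 0.0136, and adjusted p = 0.611 with an estimated correlation). The cinnamoyl-CoA reductase 1 gene FtPinG0009234700.01, of the monolignol pathway, fell from 887.7, 718.1 and 700.3 CPM in the 3 discoloration libraries to 72.7 ± 34.3 CPM (-3.40, SE 0.54, adjusted p = 0.00189). Pectin modification genes had 9 of 88 higher and 31 lower, 41 adjusted over the list alone (median -0.48, adjusted p = 0.0367, and adjusted p = 0.629 with an estimated correlation), a call lost without initial maturity library 2 (adjusted p = 0.108). Fruit dehiscence and identity genes, regulators of how fruits form and open, had 1 of 8 higher and 7 lower, 8 adjusted over the list alone (median -1.84, adjusted p = 0.0038, and adjusted p = 0.364 with an estimated correlation). A sucrose transport protein gene, FtPinG0005577300.01, fell from 197 ± 23.5 to 7.30 ± 5.11 CPM (-4.76, SE 0.58, adjusted p = 6.3e-04). Protein IQ-DOMAIN 14 (FtPinG0001537100.01) had 0 counts at initial maturity and was at least 27.7-fold lower. Copper transport protein ATX1 (FtPinG0007318600.01), with 1 count there, was 160-fold lower (95% counting interval 28.4 to 6350).

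Fewer lists passed the list test upward in this step. Cytosolic ribosome genes had 35 of 286 higher and 2 lower, and 0 adjusted over the list alone (median 0.63, adjusted p = 9.6e-07, and adjusted p = 0.751 with an estimated correlation). Most members, 249, did not pass on their own, and against no change rather than other genes (fry) the list had adjusted p = 0.203. Protease inhibitor genes had 7 of 25 higher and 3 lower, 10 adjusted over the list alone (median 1.06, adjusted p = 0.0193, and adjusted p = 0.627 with an estimated correlation), a call lost without discoloration library 1 (adjusted p = 0.0646). That call was also lost with the replicate number as a block. An endochitinase gene beside the antimicrobial peptide genes, FtPinG0008881000.01 (chromosome 6, 45187627 to 45187921), rose from 46.4 ± 10.8 to 5547 ± 3730 CPM (log2 fold change 6.90, SE 1.35, adjusted p = 0.00462). The antimicrobial peptide gene FtPinG0004979700.01 reached 69780 ± 27900 CPM (3.87, SE 1.23, adjusted p = 0.0352). The ethylene-responsive factor ERF110, FtPinG0001091900.01, rose from 38.1 ± 21.9 to 328 ± 140 CPM (3.11, SE 0.85, adjusted p = 0.0198), a call lost without discoloration library 2 or 3 or initial maturity library 2 (adjusted p = 0.0843, 0.0847 and 0.0561). Probable sesquiterpene synthase, polyol transporter 6, lipid-transfer protein 11 and psoralen synthase made up the rest of the 5 largest rises, with log2 fold changes of 5.66, 5.26, 5.10 and 5.02; that of lipid-transfer protein 11 lost its call without discoloration library 2 or 3 or initial maturity library 2 (adjusted p = 0.088, 0.0892 and 0.0549).

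In all, 8608 genes differed between initial maturity and discoloration, 3776 higher and 4832 lower. The count was 5328 and 5325 without discoloration library 2 or 3, 1663 with the closely similar pairs added together and 16195 with the libraries standing apart left out. With library totals only, 20.8% of the 9079 genes that differed were higher, against 43.9% here, and the monolignol, pectin and anthocyanin lists had adjusted p = 0.0604, 0.147 and 0.169 (medians -0.79, -0.45 and -1.11). With another description field, which matched only 44 pectin and 8 ribosome genes, these 2 lists lost their calls (adjusted p = 0.0509 and 0.115).

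Over the whole interval, from green fruit to initial maturity, most small heat shock, storage protein and oil body genes were higher. Most photosynthesis, cell division, and primary and secondary wall genes were lower. Small heat shock genes had 24 of 30 higher and 2 lower, 27 adjusted over the list alone (median 5.09, adjusted p = 8.9e-20, and adjusted p = 0.259 with an estimated correlation). The storage protein list had 17 of 23 higher and 3 lower, 21 adjusted over the list alone (median 2.25, adjusted p = 0.00213, and adjusted p = 0.611 with an estimated correlation). Without the members named for protease-like proteins 13 of 14 were higher, 13 adjusted over the list alone (median 3.29, adjusted p = 3.7e-04, and adjusted p = 0.565 with an estimated correlation). With members taken from another description field the storage median was -0.57 (adjusted p = 0.487). Oil body genes had 17 of 26 higher and 5 lower, 22 adjusted over the list alone (median 2.59, adjusted p = 0.0038, and adjusted p = 0.611 with an estimated correlation). The LEA and dehydrin list had 18 of 30 higher and 8 lower, 26 adjusted over the list alone (median 1.89, adjusted p = 0.0191, and adjusted p = 0.611 with an estimated correlation). Protease inhibitor genes had 16 of 25 higher and 6 lower, 22 adjusted over the list alone (median 1.92, adjusted p = 0.0038, and adjusted p = 0.611 with an estimated correlation). ERF098 (FtPinG0009155900.01) was at least 2710-fold higher, reticuline 7-O-methyltransferase (FtPinG0006556600.01) at least 1230-fold and beta-glucosidase 17 (FtPinG0003438100.01) at least 964-fold.

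At the other end, 51 of 55 photosynthesis genes fell and 1 rose, with 52 adjusted over the list alone (median -5.33, adjusted p = 1.0e-27, and adjusted p = 0.484 with an estimated correlation). Cell division genes had 7 of 95 higher and 71 lower, 82 adjusted over the list alone (median -2.46, adjusted p = 2.8e-06, and adjusted p = 0.663 with an estimated correlation). Primary wall growth genes had 9 of 57 higher and 39 lower, 48 adjusted over the list alone (median -2.54, adjusted p = 9.4e-04, and adjusted p = 0.611 with an estimated correlation). Secondary wall genes had 5 of 30 higher and 22 lower, 27 adjusted over the list alone (median -2.82, adjusted p = 0.00945, and adjusted p = 0.674 with an estimated correlation). Pectin modification genes had 17 of 88 higher and 47 lower, 68 adjusted over the list alone (median -1.41, adjusted p = 0.0038, and adjusted p = 0.611 with an estimated correlation). Laccase genes had 2 of 19 higher and 14 lower, 16 adjusted over the list alone (adjusted p = 0.0284, and adjusted p = 0.627 with an estimated correlation). Their median log2 change was -5.72 as fitted and -3.64 with members at 0 counts set to their bound. Their summed CPM moved far less, at 551.7 in green fruit, 403.7 at discoloration and 449.6 at initial maturity. Class III peroxidase genes had 10 of 36 higher and 20 lower, 30 adjusted over the list alone (median -1.53, adjusted p = 0.0257, and adjusted p = 0.627 with an estimated correlation), a call lost without green fruit library 2 or 3, any 1 discoloration library or initial maturity library 2 (adjusted p = 0.0626 to 0.166). With library totals only the adjusted p was 0.799 for laccase genes, 0.903 for peroxidase genes and 0.293 for each of the secondary wall, primary wall and pectin lists. Their medians against all genes were then -5.65, -1.51, -2.87, -2.54 and -1.38. Protein ECERIFERUM 1 (FtPinG0009513400.01), of wax synthesis, was 2420-fold lower (95% counting interval 434 to 95600), and IQ-DOMAIN 14 (FtPinG0001537100.01) at least 640-fold lower.

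In all, 14361 genes differed between initial maturity and green fruit, 6691 higher and 7670 lower. The count was 9183 with the closely similar pairs added together, 8971 of them among the 14361. With library totals only, 10.7% of the 19519 genes that differed were higher, against 46.6% here.

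**Figure D2:**
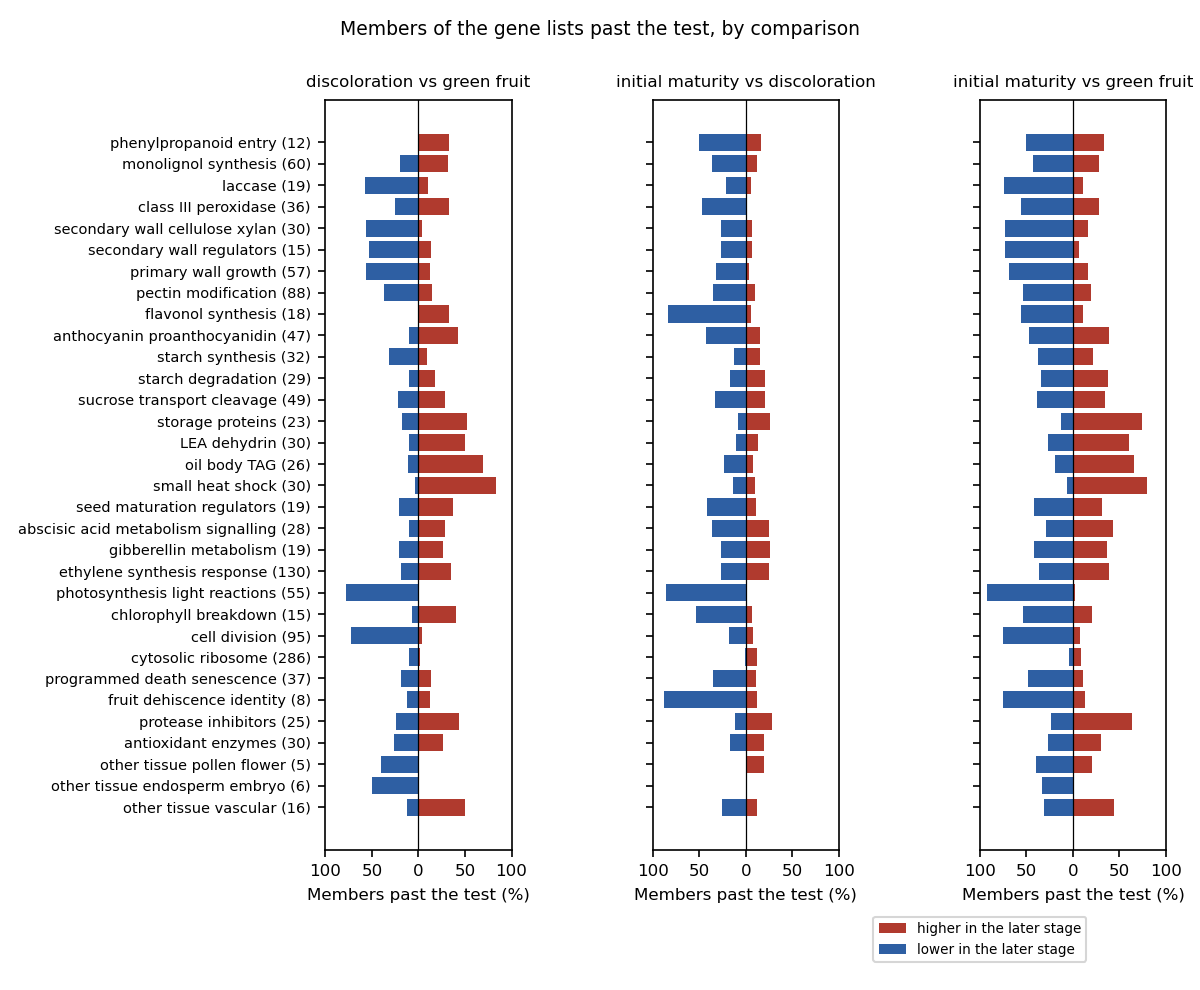
For each gene list (tested members in brackets) and comparison, bars give the percent of tested members past the gene-level test, higher in the later stage to the right and lower to the left. Small heat shock genes lay to the right at discoloration against green fruit (25 of 30 higher), and photosynthesis genes to the left in each comparison (43, 47 and 51 of 55 lower).

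**Figure D3:**
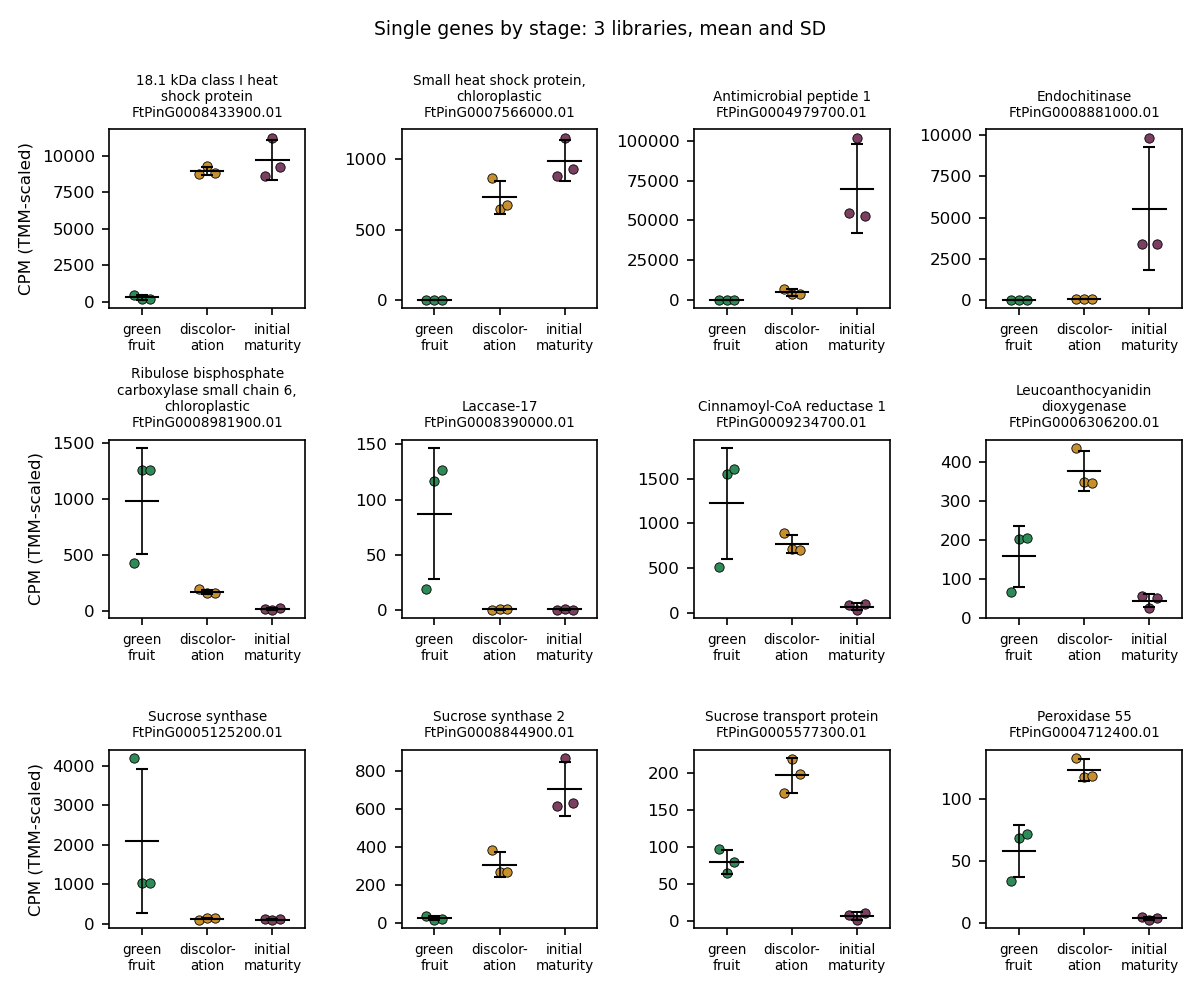
TMM-scaled CPM of 12 named genes by stage on linear axes, with a point for each library and lines for the mean and SD (n = 3). Antimicrobial peptide 1 (FtPinG0004979700.01) had means of 7.29, 4765 and 69780 CPM and the Rubisco small chain gene FtPinG0008981900.01 means of 983, 172 and 18.1 CPM.

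Other lists passed the list test in no comparison with the settings used here, but some did with others. With another description field pollen and flower markers passed upward against green fruit (median 1.43, adjusted p = 0.0222 at discoloration, and 3.76, adjusted p = 0.00769 at initial maturity). That field matched only 4 genes for this list. The list by Swiss-Prot names, with 5 tested genes, had medians of -0.52 and -0.09 and did not pass, so no rise of such markers is shown. Abscisic acid and vascular genes passed in that field at discoloration against green fruit (0.0429 and 0.0301), and phenylpropanoid entry genes and seed maturation regulators in the next step (0.0365 and 0.0493). Secondary wall regulators passed downward at initial maturity against green fruit with the replicate number as a block (0.0387), with close pairs added together (0.0337) and without green fruit library 1 (0.00305) or discoloration library 2 or 3 (0.0447 and 0.0445). At discoloration against green fruit they passed with the block (0.0331), with pairs added together (0.0452) and without green fruit library 1 (2.5e-04) or initial maturity library 1 or 3 (0.0436 and 0.0467). Starch synthesis genes passed downward there without green fruit library 2 or 3 (0.0336 and 0.035) and with pairs added together (0.0477). With library totals seed maturation regulators, abscisic acid and gibberellin genes passed upward there (0.0479, 0.043 and 0.0276), and gibberellin genes over the whole interval (0.0151). With fry, against no change, 28 results over all lists passed that had not. For initial maturity against green fruit, phenylpropanoid entry had 4 of 12 genes higher and 6 lower (10 adjusted over the list alone, adjusted p = 0.858) and secondary wall regulators 1 of 15 higher and 11 lower (12, adjusted p = 0.0631). Starch synthesis had 7 of 32 higher and 12 lower (19, adjusted p = 0.658), starch degradation 11 of 29 higher and 10 lower (22, adjusted p = 0.633), and sucrose transport and cleavage 17 of 49 higher and 19 lower (37, adjusted p = 0.775). Seed maturation regulators had 6 of 19 higher and 8 lower (14, adjusted p = 0.923), abscisic acid genes 12 of 28 higher and 8 lower (20, adjusted p = 0.442), and gibberellin genes 7 of 19 higher and 8 lower (16, adjusted p = 0.384). Programmed death genes had 4 of 37 higher and 18 lower (22, adjusted p = 0.174) and antioxidant enzymes 9 of 30 higher and 8 lower (17, adjusted p = 0.901). Among markers of other tissues, pollen and flower had 1 of 5 higher and 2 lower (3, adjusted p = 0.853), endosperm and embryo 0 of 6 higher and 2 lower (2, adjusted p = 0.548), and vascular tissue 7 of 16 higher and 5 lower (12, adjusted p = 0.504). The median and the test differed in sign for anthocyanin genes in this comparison (-0.60, test upward, adjusted p = 0.495), and for sucrose (-0.08), abscisic acid (-0.04) and vascular (-0.09) genes, whose tests also pointed upward. For seed maturation regulators the median was 0.11 and the test pointed downward.

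Whether genes changed alike in both intervals was tested directly, and 4730 genes changed differently, 1556 with a higher and 3174 with a lower change in the later interval. This count was 144 with the closely similar pairs added together, 4 with a higher and 140 with a lower change later, and 14533 with the libraries standing apart left out. It was 8017 without green fruit library 1, 1979 without discoloration library 2 and 2012 without discoloration library 3. With library totals only, 72.2% of the 6648 genes had the higher change in the later interval, against 32.9% here. Of genes past the threshold in both intervals, 1171 rose in both and 1448 fell in both, where independent lists would share 737 and 963. Another 730 rose and then fell (944 for independent lists) and 579 fell and then rose (753). Counts simulated with no stage effect gave a mean of 0 in each of these classes, but also left a mean of 22896 genes changed in neither interval. They therefore set no chance level for genes that do change in 1 interval. Both intervals share the discoloration libraries, which enter them with opposite sign, so shared noise would add genes that change in opposite directions; 3 libraries are too few to split. Any difference among the stages was found for 15460 genes.

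The authors' deposited table called 4874 genes for discoloration against green fruit, 2645 of them higher at the later stage. For initial maturity against discoloration the authors' deposited table called 7272, with 3008 higher, and for initial maturity against green fruit 7789, with 3204 higher. Of the calls in the authors' deposited table among gene models tested here, 97.8%, 88.4% and 99.7% were also called here in the same direction, and 0 in the opposite one.

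Genotype calls were compared to see whether replicate numbers mark plants. Over 83860 SNP sites, same-numbered libraries of different stages had equal calls at 85.49% of sites, against a mean of 85.45% over the 36 ways to match the numbers (exact permutation test, one-sided, p = 0.083, smallest possible 0.028). Over InDel sites the share was 91.27%, the highest of the 36 (exact permutation test, one-sided, p = 0.028). With only calls whose number was at least 20, an alternative chosen after seeing the data, the exact p was 0.167 for SNPs and 0.917 for InDels.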

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

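The lists with members left out by name, the close pairs added together and the tests of why libraries stand apart, of a few genes taking most counts, of scaling and of reads shared between related genes were chosen after the results were seen. The count of the interval difference, the lists and the single genes below were singled out because the change in the later interval differed from that in the earlier one. The other counts are given beside it, and the libraries standing apart and the shift under library totals were picked after their values were seen.

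The number of genes whose change differed between the intervals was 4730. Of 100 splits of the 9 libraries, the real one included, 1 gave as many, and the highest of the others gave 968. These splits mix libraries of different stages, so they test against no stage difference at all. They cannot decide whether the changes of the 2 intervals differ. Each stage also holds a close pair, and with those pairs added together the count was 144. For any difference among the stages 1 of 100 splits gave as many as the real 15460, with 5176 in the highest other split. Chance can be excluded there only where the 9 libraries are taken as independent, which the close pairs put in doubt. With the pairs added together that count was 8006. For the comparisons of 2 stages the real counts were 9326, 8608 and 14361 and the highest of the other splits gave 0, but 10 splits are too few for a share under 0.05.

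Lists with a change in the later interval below that in the earlier one were small heat shock (camera, adjusted p = 2.0e-37), flavonol (7.5e-09), anthocyanin and proanthocyanidin (2.8e-06), oil body (3.6e-06), class III peroxidase (5.3e-04), photosynthesis (0.00371), monolignol (0.00441), chlorophyll breakdown (0.00521), phenylpropanoid entry, LEA and dehydrin and fruit dehiscence (0.0197 each), seed maturation regulators (0.0333) and ethylene (0.0427). Those with a higher change later were cytosolic ribosome (7.5e-09), cell division (5.8e-06), starch synthesis (0.0197) and secondary wall (0.0373). With an estimated correlation small heat shock and anthocyanin genes passed (adjusted p = 0.0135 each). With members left out by name only small heat shock genes passed this (adjusted p = 0.0217, against 0.129 for anthocyanin genes), and with the close pairs added together neither list did (adjusted p = 0.131 each). At the preset correlation, ethylene genes lost their call with members left out (0.184) and storage proteins gained one (0.00521), while with the pairs added together secondary wall genes (0.133), seed maturation regulators (0.0739) and ethylene genes (0.0739) lost theirs.

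Single genes with a lower change in the later interval (edgeR, adjusted p of the difference) included small heat shock protein, chloroplastic (1.2e-04), beta-fructofuranosidase (2.4e-04), peroxidase 55 (2.9e-04), reticuline 7-O-methyltransferase (3.8e-04), the sucrose transport protein (0.00186), antimicrobial peptide 1 FtPinG0004980500.01 (0.00279), leucoanthocyanidin dioxygenase (0.00399), beta-glucosidase 17 (0.00434) and 18.1 kDa heat shock protein (0.00492). Further ones were pectinesterase/inhibitor 36 (0.00605), xyloglucan endotransglucosylase 23 (0.00937) and 24 (0.011), pectinesterase 2 (0.0116), sucrose synthase 2 (0.0125), L18a-like protein (0.0163), beta-D-xylosidase 4 (0.0184), cationic peroxidase 1 (0.0213), GDSL esterase At1g29660 (0.029), ERF098 (0.0379) and the cinnamoyl-CoA reductase 1 genes FtPinG0000983500.01 (0.041) and FtPinG0009234700.01 (0.0465). ERF098, beta-glucosidase 17 and reticuline 7-O-methyltransferase had 0 counts in all green fruit libraries. Their earlier folds are only bounds, so the size of their fitted log2 differences (-3.80, -10.75 and -7.71) is uncertain. A higher change later was found for GDSL esterase At5g45950 (0.00666), proline-rich protein 4 (0.0195), 60S acidic ribosomal protein P3 (0.0255), laccase-17 (0.0268), sucrose synthase FtPinG0005125200.01 (0.0308) and early nodulin-like protein 2 (0.0324). Of these, GDSL esterase At5g45950, proline-rich protein 4, laccase-17 and early nodulin-like protein 2 were already at 0.170, 0.155, 0.450 and 0.319 CPM at discoloration. They had little room to fall further, and none passed in the later interval (edgeR, adjusted p = 0.772, 0.307, 0.984 and 0.897). With the close pairs added together 4 of the 21 genes with a lower change later passed. Of the 6 with a higher one 0 passed (edgeR), with adjusted p of 0.0696 to 0.24.

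In each stage 1 library stood apart from a close pair. That a library was deposited more than once is argued against by the smallest chi-square per degree of freedom, 2.02, which is beyond sampling noise. Seeds further along the same development could give such a library. Over genes, its difference from the pair and the change of the stage interval had r = 0.439 in green fruit, 0.371 at discoloration and 0.134 at initial maturity. The close pair entered both terms, with the same sign in the first 2 stages and the opposite sign at initial maturity. That tends to raise the first 2 values and lower the last by construction, so they do not decide. A pair made from the same plant might also look so, but the close pair had the most equal SNP calls in 1 of 3 stages, which leaves this open. No biological explanation was tested beyond these.

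Scaled by library totals, most genes were lower at the later stages. A few genes taking most of the counts is consistent with this: for discoloration against green fruit the median log2 difference of all genes was -0.19 with the 50 most-counted genes left out of the totals, 18.9% of its size with full totals, and -0.02 with TMM. Whether total RNA per seed also changed was not tested.

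Small heat shock genes were higher at discoloration than in green fruit. A summed CPM of the list that rose by a log2 change of 4.96 argues against reads merely moving between its members. The 18.1 kDa gene FtPinG0008433900.01 held most of that sum, 299 of 403 CPM in green fruit and 8953 of 12530 at discoloration. The sum therefore cannot tell a rise of many members from reads of this gene counted on related ones. Scaling is argued against for the median of the list, whose log2 change was at least 4.22 under 4 scalings, with a lower 95% limit of at least 1.98, while the scalings moved the median of all genes by 0.99. That limit is over the 30 genes taken as independent, not over libraries, and their estimated correlation was 0.199. For the members that rose least scaling stays open, since the lower quartile was 0.88 with library totals, under the bound of 1 set first for the list as a whole. A test planned beforehand, of the list median against that of all genes, was void, since a factor moves both alike. Acute heat or handling stress of the later seeds could not be told apart from development: the median log2 change of 22 HSP70 and HSP90 genes was 0.08, but 9 rose, each by a log2 change over 1, and 2 fell. A bound of 0.5 on that median had been set beforehand to argue against stress; it was a wrong bound, since the genes moved both ways. Seed maturation remains a candidate explanation and was not tested apart from stress.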

How the results depend on the processing

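Adding the closely similar libraries together, leaving out the libraries standing apart, leaving out list members by name and the genotype call minimum were chosen after seeing the data. Counts of genes kept within 1.5 times under DESeq2, its size factors, upper-quartile factors, voom, other filters, and without the 50 most-counted genes or the genes outside the reference annotation. They moved beyond that as follows, and the cause was not tested except that stricter thresholds lower counts by construction. Discoloration against green fruit (9326) gave 17967 with library totals only, 17988 and 17763 on log2(FPKM + 1) and log2(FPKM + 0.1), 5337 at an adjusted p of 0.01 and 5380 against a 1.5-fold change. Initial maturity against discoloration (8608) gave 4317 and 4296 at these thresholds and 5682 with a 2-fold minimum. The interval difference (4730) gave 7774 and 7107 on FPKM, 1812 and 3105 at the thresholds. With close libraries added together the counts were 2877, 1663, 9183 (initial maturity against green fruit), 144 (interval difference) and 8006 (any stage). With libraries standing apart left out they were 17730, 16195 and 14533 (interval difference). Leaving out each library in turn gave 6735 to 12436, 5325 to 12190, 12438 to 16664, 1979 to 8017 (interval difference) and 13522 to 18180 (any stage). With a 2-fold minimum 573 genes rose in both intervals, 413 rose then fell and 255 fell then rose. Of lists, all 36 calls were lost with an estimated correlation, 11 with library totals only (8 gained) and 3 with fry (28 gained). The ribosome median for discoloration against green fruit ran from -0.51 to 0.18 over libraries left out. In another description field the direction of the list test turned for 4 results that passed in 1 of the 2 fields. Storage proteins went to a median of 0.11 (test downward) at discoloration and -0.57 at initial maturity against green fruit. Pollen and flower markers, with only 4 genes matched in that field, went to 1.43 and 3.76 there and passed (adjusted p = 0.0222 and 0.00769). In that field, the KEGG text, 10 list calls were lost and 9 gained, on other and mostly smaller sets of genes. Of 69 named gene results DESeq2 kept all 63 it tested. Leaving out discoloration library 2 or 3 lost 9 of these calls each. Leaving out discoloration library 1 or any 1 initial maturity library lost 5 each. Without green fruit library 2 or 3, 2 were lost, and without green fruit library 1, 0. Histone H3.3 (FtPinG0005843900.01) turned to -0.39 with library totals and on FPKM. The genotype match over InDels gave an exact p of 0.028; every site had a call in all 9 libraries, so the planned limit to such sites was not run. The count filter left 10300 genes untested, and whether depth or absent expression kept their counts low was not tested.

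The replicate number as a block gave 8485, 7848, 13872, 4081 (interval difference) and 14614 (any stage) genes. The pairing check found deviation correlations from -0.14 to 0.13 over 9 same-numbered pairs, 2 of them over 0.1, so the numbers were not taken to pair samples. Under the block 3 list calls were lost: ribosome genes at discoloration against green fruit (adjusted p = 0.0924), and anthocyanin (0.0643) and protease inhibitor genes (0.0763) at initial maturity against discoloration. Gained were laccase (adjusted p = 0.00305) and secondary wall regulator genes (0.0331) at discoloration against green fruit, the latter also at initial maturity against green fruit (0.0387), and primary wall growth genes at initial maturity against discoloration (0.0295), and 3 of 69 named gene calls were lost.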

Other observations

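The gene groups and genes here, and their tests, were chosen after values were seen; list tests were adjusted over 30 tests. Microtubule genes (kinesins and tubulins, which build and move along the spindle and cell cortex) fell at discoloration against green fruit in 51 of 82 members and rose in 7, with a median log2 change of -1.38 (camera, adjusted p = 8.3e-08, and adjusted p = 0.163 with an estimated correlation). Chitinase genes rose in 11 of 15 members and fell in 1 (2.68, adjusted p = 0.0014, and adjusted p = 0.241 with an estimated correlation). Heat stress transcription factor genes rose in 13 of 27 and fell in 1 (0.68, adjusted p = 0.0024, and adjusted p = 0.163 with an estimated correlation), and WRKY genes rose in 23 of 68 and fell in 7 (0.40, adjusted p = 0.00723, and adjusted p = 0.269 with an estimated correlation). These 3 groups did not pass in the next step, with 4 higher and 4 lower, 3 and 8, and 9 and 18 (adjusted p = 0.928, 0.716 and 0.79), nor over the whole interval (adjusted p = 0.0543, 0.0807 and 0.126). At initial maturity against green fruit, cuticle and wax genes fell in 53 of 100 and rose in 17 (-1.26, adjusted p = 3.7e-04, and adjusted p = 0.163 with an estimated correlation), and aquaporin genes fell in 20 of 32 and rose in 5 (-2.03, adjusted p = 3.7e-04, and adjusted p = 0.269 with an estimated correlation). Probable aquaporin TIP3-2 (FtPinG0005321900.01), among the 20 most-counted genes, rose from 734.5 to 7732 CPM (log2 fold change 3.40, edgeR adjusted p = 0.00281). The fall in most members is thus not a fall in summed aquaporin counts, which were not compared. Fatty acid synthesis genes fell in 19 of 44 and rose in 0 at initial maturity against discoloration (-0.56, adjusted p = 0.00663, and adjusted p = 0.372 with an estimated correlation), and did not pass in the other comparisons (adjusted p = 0.912 and 0.123).

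The cellulose synthase genes of secondary walls fell together at discoloration. Subunit 4 (FtPinG0000375900.01) fell from 186 ± 140 CPM by a log2 fold change of -5.52 (SE 0.86), subunit 8 (FtPinG0002305900.01) fell from 148 ± 114 to 3.58 ± 2.17 and subunit 7 (FtPinG0003961800.01) from 99.6 ± 74.8 to 2.87 ± 1.54 (n = 3, edgeR adjusted p = 0.0013, 0.00199 and 0.00187). Among seed maturation regulators, FUS3 (FtPinG0003428600.01) rose from 53.7 ± 41.7 to 184 ± 19.7 CPM and then fell to 63.7 ± 9.06 (adjusted p = 0.0126 and 0.0259), while ABI5 (FtPinG0003523300.01) went from 21.8 ± 15.8 to 138 ± 17.9 and 300 ± 13.0 CPM (adjusted p = 0.00163 and 0.0593). A gibberellin 2-beta-dioxygenase gene (FtPinG0007406000.01), of gibberellin breakdown, had log2 fold changes of -0.04 (adjusted p = 0.933) and 4.34 (adjusted p = 1.0e-04) in the earlier and later interval and reached 81.2 ± 33.3 CPM, and the difference between intervals had an adjusted p of 0.00106.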
